A study of Homo sapiens with 6 samples.

How the data were processed

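Small RNA was profiled by sequencing in BE(2)C and Kelly, both human neuroblastoma cell lines, with 3 libraries per line. Per the labels, cells were untreated and harvested before confluence, total RNA was extracted with Trizol, and libraries were made with an NEBNext small RNA kit and size-selected for miRNA. The 3 libraries of a line carried synthetic spike-in RNAs at labelled concentrations of 500, 50 and 5, for which no unit is given, and these are named replicates 1, 2 and 3. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical. The amount of RNA put into each library is not given in the sources used here.

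The authors deposited one table of log10 values with a column per library, 2588 human mature miRNA rows and 6 spike-in rows. The log10 values are of TPM + 1, since 10 raised to each value, minus 1, sums to 1000000 in every column with the spike-ins included. The submitters' processing notes name HISAT 0.1.6, Salmon 0.3.2 and the GRCh38 build. Their roles, the miRNA reference, trimming, filters and whether strand was used are not given in the sources used here. Closely related miRNAs, such as let-7a and let-7c, differ by few bases, so reads can be split between their rows in a way that cannot be checked. The same holds for rows from opposite strands of one locus.

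TPM was rebuilt from the deposited values and rescaled to 1000000 over miRNA rows alone. All levels below are on this scale and are called TPM. The spike-ins took 34.4%, 3.48% and 0.395% of the deposited TPM in BE(2)C and 40.7%, 6.89% and 0.532% in Kelly at levels 500, 50 and 5, so unscaled values are not comparable between libraries. Low values fell on steps of a library constant divided by a mature length of 20 to 23 nucleotides. From these steps depth was estimated at 338573 to 702512 reads per library, of which 315245 to 478020 were miRNA reads. With the length of each row chosen from the data, 3927 of 4336 values under 30 reads came out whole within 0.02 reads, or 90.6%. These reads are estimates. They also underlie the floor given next, the depths of the simulated reads and the chi-square between libraries. The tests between lines used them in only 1 added alternative. A read of 22 nucleotides was worth 2.09 to 3.17 TPM, and a floor of 3 reads lay at 6.28 to 9.52 TPM. The floor covers counting error only.

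Lines were compared with limma 3.58.1 in R 4.3.3 (linear models with an intensity trend) on log2(TPM + 1), for miRNAs at 1 TPM or more in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low miRNAs. No fold is given against a line whose mean lies under the floor. The same model with log10 spike-in concentration as a term and the line as covariate tested for miRNAs that moved with spike-in level. Arm ratios were tested with limma on log2((5p + 0.5)/(3p + 0.5)) for hairpins with both arms at a mean of 10 TPM or more. Of 21 miRNA lists, 18 had at least 3 measured products and were tested with camera at a preset correlation of 0.01. A product is one mature arm. Single values were compared with exact two-sided permutation tests in scipy 1.17.1, for which 3 against 3 libraries cannot give a p below 0.1. Spike-in slopes are of log10 TPM on log10 concentration. The table held no raw counts, so the count models written for that case (edgeR, DESeq2 and voom on counts) were not run. For this unit, scaling by total is the main scaling itself.

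The designs, the lists, most alternatives and the rule for named miRNAs were fixed before the data were examined. The rule names all let-7 family products. It adds the 10 largest changes in each direction among miRNAs past the threshold, at 100 TPM or more in the higher line and with no overlap between lines. It also takes the 5 most abundant miRNAs of each line, up to 4 members of each list, every spike-in, and up to 3 arm ratios and 3 spike-in slopes in each direction. Names outside the rule are marked as chosen after their values were seen. The alternatives fixed beforehand were quantile normalization, spike-in scaling, other filters and pseudocounts, a 2-fold minimum, the spike-in level as a block, summed arms, each library left out, and other list tests. Median-ratio scaling, the deposited TPM with spike-ins, voom on estimated reads, single spike-ins, and the omission of both level 500 libraries or of single rows were added after the data were seen.

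The scripts were tested on simulated reads drawn from the observed means and depths with a dispersion of 0.05. In the first version of the comparison of lines, any miRNA at 10 TPM or more could change, including the most abundant ones. It recovered 38.8%, 80.6% and 97.0% of 2-, 4- and 8-fold changes, but 202 of 954 unchanged miRNAs were called, because changes of abundant miRNAs shifted all others under scaling by total, with a median log2 change of -0.85. With median-ratio scaling of the same simulated data, 13 were called. A second version left the 30 most abundant miRNAs unchanged. It recovered 43.3%, 89.6% and 97.0%, with 1 false call among 1032. The second version was written after the result of the first was seen and represents the easier case. In the real data abundant miRNAs do differ between the lines, so the first case applies at least in part and calls with small changes are uncertain. For slopes of 4-fold per unit of log10 concentration, 99.0% were recovered among 1231 miRNAs, with 2 false calls. For 4-fold changes of arm ratios, 89.3% were recovered among 108 hairpins, with 0 false calls. A 2-fold shift of the 14q32 list was recovered with 0 false calls among the 17 other lists.

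Genomic positions are from GENCODE 29 on GRCh38, matched by miRNA gene name. Libraries of a line differed by more than sampling noise, with a chi-square of 5.61 to 62.3 per degree of freedom, so no pair of libraries holds the same reads.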

Results

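The data comprise mature miRNA levels in 6 libraries, 3 from BE(2)C and 3 from Kelly. Both are established neuroblastoma cell lines that carry MYCN amplification. The series title states an interest in how let-7 miRNAs are made and act in neuroblastoma. Estimated depth was 632221, 479164 and 425312 reads in the BE(2)C libraries with spike-ins at 500, 50 and 5, and 702512, 338573 and 480575 reads in the matching Kelly libraries. Between 977 and 1317 miRNA rows were above 0 in a library. Levels are TPM over miRNA rows, as mean ± SD of 3 libraries (n = 3).

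The 2 lines were led by different miRNAs. In BE(2)C the most abundant were miR-381-3p (105976 ± 3088 TPM), miR-127-3p (67952 ± 6132), miR-92a-3p (57846 ± 3000), miR-27b-3p (55977 ± 2353) and miR-370-3p (47565 ± 949). Of these 5, miR-381, miR-127 and miR-370 lie in the imprinted miRNA cluster at 14q32. In Kelly the most abundant were miR-3529-3p (177312 ± 38374), miR-375 (126191 ± 8347), miR-92a-3p (125312 ± 10856), miR-129-5p (53931 ± 20132) and miR-99b-5p (30005 ± 4896). The miR-3529 hairpin lies on the strand opposite miR-7-2, so reads of miR-7-5p and miR-3529-3p cannot be told apart where strand was not used. The 10 most abundant miRNAs held 49.3% ± 1.23 of miRNA TPM in BE(2)C and 63.9% ± 4.99 in Kelly.

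The first comparison was of how much let-7 each line held. The let-7 family represses growth genes such as MYCN and LIN28B. Its guide arms made up 3.98% ± 0.101 of miRNA TPM in BE(2)C and 2.31% ± 0.350 in Kelly, a ratio of 1.72, with no overlap between the libraries. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The ratio was 1.46 when miR-3529-3p was left out of the total. The total also held the 14q32 products, at 39.7% in BE(2)C and 0.344% in Kelly. They lower the let-7 share mainly in BE(2)C. A ratio without them was not computed, so 1.46 and 1.72 need not bound the difference. Relative to spike-in TPM times concentration, let-7 guides stood at 47.6 ± 7.73 in BE(2)C and 17.9 ± 2.97 in Kelly, a ratio of 2.66 (exact p = 0.1). By the same measure all miRNAs together stood at 1201 ± 222 and 780 ± 137, a ratio of 1.54. Single spike-ins gave let-7 ratios from 1.39 (mirNegDH1, exact p = 0.6) to 3.52 (MIR17, exact p = 0.1). As the RNA input is not stated, this measure need not reflect the amount per cell.

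Of 16 let-7 family products, 6 were lower in Kelly and 0 were higher (7 and 0 when adjusted over the list alone). The let-7c-5p guide, from an intron of MIR99AHG (chromosome 21, 16539828 to 16539911), stood at 1314 ± 231 TPM in BE(2)C and 29 ± 5.09 in Kelly (log2 change -5.45, SE 0.25, limma adjusted p = 1.16e-06). Its passenger let-7c-3p was at 30.7 ± 2.13 in BE(2)C and listed at 0 in all 3 Kelly libraries. The let-7b-5p guide (chromosome 22, 46113686 to 46113768, overlapping an exon of MIRLET7BHG) fell from 2918 ± 464 to 581 ± 32.6 (log2 change -2.32, adjusted p = 2.86e-05). The most abundant member, let-7a-5p, which is made from loci on chromosomes 9, 11 and 22, was at 21103 ± 694 and 10706 ± 2290 (log2 change -0.999, adjusted p = 0.00409). Its call was lost on the deposited TPM (adjusted p = 0.0975, the highest of the alternatives, whose lowest was 0.000149). The let-7i-5p guide (chromosome 12, 62603686 to 62603769) was at 2341 ± 714 and 1169 ± 183 (log2 change -0.97, adjusted p = 0.0238). The let-7d-5p guide passed narrowly at 73.6 ± 12.7 and 34.6 ± 5.74 (adjusted p = 0.0400), a call lost without BE(2)C replicate 1, 2 or 3 or Kelly replicate 1 or 3 (adjusted p 0.0703 to 0.180, and 0.00902 to 0.211 over all alternatives). The call was also lost with the spike-in level as a replicate block (adjusted p = 0.0614), with quantile normalization (0.0631), without a filter (0.0934), without the level 500 libraries (0.174) and on the deposited TPM (0.211). Without Kelly replicate 3, let-7i-5p gave an adjusted p of 0.0515, and quantile normalization reduced its log2 change to -0.16 (adjusted p = 0.755, with a lowest value of 0.00282 among the alternatives). Its call was lost on the deposited TPM too (adjusted p = 0.0755).

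The remaining let-7 guides did not pass. These were let-7f-5p (6976 ± 255 TPM in BE(2)C and 5037 ± 531 in Kelly, adjusted p = 0.0555), let-7e-5p (2248 ± 65.2 and 2531 ± 407), let-7g-5p (2750 ± 128 and 2986 ± 506) and miR-98-5p (50.4 ± 20.8 and 35.7 ± 7.57). Fitted log2 changes of 0.16 for let-7e-5p and 0.11 for let-7g-5p turned to -0.46 and -0.51 with spike-in scaling and to -0.17 and -0.22 with median-ratio scaling. That of let-7f-5p turned from -0.47 to 0.28 with quantile normalization. Within the family, let-7a-5p held 53.1% ± 2.93 of guide TPM in BE(2)C and 46.1% ± 2.82 in Kelly. The shares of let-7e-5p were 5.65% ± 0.197 and 10.9% ± 0.305, and those of let-7g-5p 6.91% ± 0.260 and 12.9% ± 0.854. Each of these 3 shares gave an exact p of 0.1, or 0.15 when adjusted over the 9 guides.

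**Figure D1:**
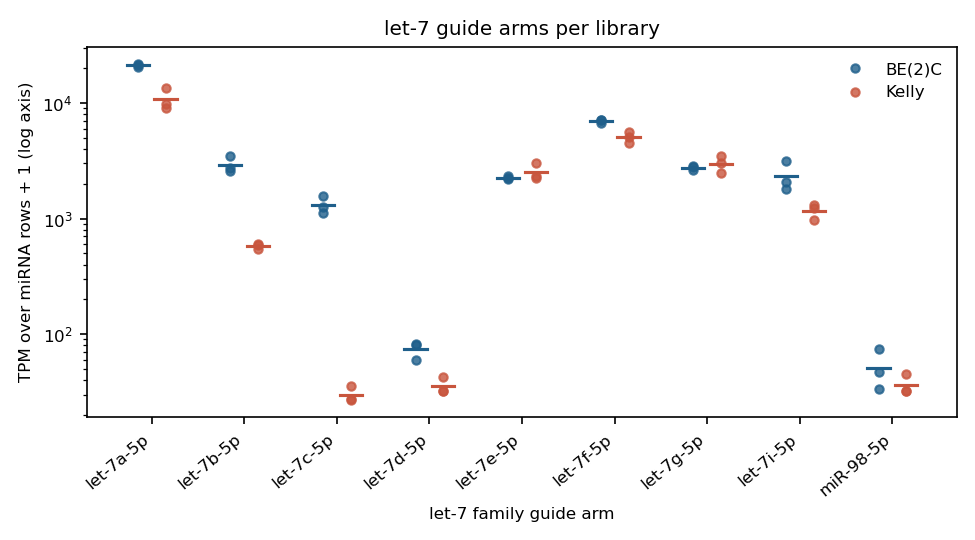
TPM over miRNA rows + 1 (log axis) of the 9 let-7 family guide arms, with a point per library and a bar at the mean of 3 libraries. The libraries of BE(2)C lie above those of Kelly for let-7a-5p, let-7b-5p, let-7c-5p, let-7d-5p, let-7f-5p and let-7i-5p, of which let-7f-5p did not pass and turned direction with quantile normalization.

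Binding of LIN28 to let-7 precursors with a CSD motif is known to block their processing. Among products of let-7 members with such a site (let-7b, let-7d, let-7g, let-7i and miR-98), 3 of 8 were lower in Kelly, also when adjusted over the list alone. The camera adjusted p was 0.0212, and the adjusted p with an estimated correlation was 0.513. Among products of members without the site (let-7a, let-7c and let-7e), 3 of 6 were lower, again also over the list alone (adjusted p = 0.0285, and 0.518 with an estimated correlation). Whether these lists differ from each other was not tested. The whole family was lower by camera (adjusted p = 0.00160), a call lost with an estimated correlation (adjusted p = 0.513).

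Across all miRNAs, 292 of 1217 tested differed between the lines by limma, 152 higher in Kelly and 140 higher in BE(2)C. The largest rises in Kelly included miR-335-3p, from an intron of MEST (1762 ± 204 TPM, against 2.38 ± 2.36 in BE(2)C, under the floor). Its other arm miR-335-5p was at 137 ± 26.1 and listed at 0 in all 3 BE(2)C libraries. The p53-induced miR-34a-5p was at 461 ± 210 in Kelly and 2.29 ± 2.36 in BE(2)C, and miR-34c-5p at 119 ± 4.33 and listed at 0. Brain-enriched miR-129 rose through miR-129-2-3p (77.4 ± 10.3 to 2491 ± 811), miR-129-1-3p (157 ± 62.5 in Kelly, under the floor in BE(2)C) and miR-129-5p (3162 ± 117 to 53931 ± 20132, log2 change 4.02, SE 0.27). Further rises were those of miR-592, in an intron of GRM8 (56.9 ± 19.8 to 941 ± 315), miR-28-5p (20.9 ± 14.4 to 196 ± 30.5) and miR-3180-3p (6.93 ± 0.393 to 191 ± 35.0). The neuroendocrine miR-375 rose from 22375 ± 5283 to 126191 ± 8347 (log2 change 2.52, SE 0.19). The call of miR-92a-3p, with a log2 change of 1.11, was lost with spike-in scaling (log2 change 0.49, adjusted p = 0.299, the highest of the alternatives, whose lowest was 1.1e-06), with quantile normalization (log2 change 0.50, adjusted p = 0.174) and on the deposited TPM (adjusted p = 0.0833).

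Toward BE(2)C, the largest change outside 14q32 among miRNAs at 100 TPM or more was that of miR-99a-5p, in an intron of MIR99AHG beside let-7c (chromosome 21, 16539089 to 16539169). It stood at 11710 ± 355 TPM in BE(2)C and 18.0 ± 5.57 in Kelly (log2 change -9.31, SE 0.25, adjusted p = 1.15e-07). From the same host gene, miR-125b-2-3p was at 77.7 ± 21.1 and 16.4 ± 2.25 (log2 change -2.15).

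The split of calls depended on scaling. The share of calls higher in Kelly was 52.1% in the main comparison, 62.4% with quantile normalization, 40.5% with median-ratio scaling, 40.4% on the deposited TPM and 30.3% with spike-in scaling, which shifted the median log2 change by -0.49. Median-ratio scaling kept 246 of the 292 calls and spike-in scaling 207, and simulated changes of abundant miRNAs produced false calls under the main scaling. The median log2 change over the 1217 tested miRNAs was 0.36 in the main comparison, so rises of that size in Kelly need not be particular to a miRNA. Single libraries mattered too. Without BE(2)C replicate 2 there were 194 calls, of which 100 were higher in Kelly. Without Kelly replicate 3, 82 were higher in Kelly, and without BE(2)C replicate 3, 93 were higher in BE(2)C.

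The 14q32 cluster set the lines apart most broadly. Of its 79 measured products (chromosome 14, 100852390 to 101066801), 72 were higher in BE(2)C and 0 in Kelly (75 and 0 when adjusted over the list alone). Together they held 39.7% ± 1.49 of miRNA TPM in BE(2)C and 0.344% ± 0.0559 in Kelly. Examples are miR-127-3p (67952 ± 6132 and 268 ± 22.5, log2 change -7.98, SE 0.16), miR-433-3p (5555 ± 666 and 29.2 ± 11.1), miR-136-3p (7780 ± 1068 and 25.0 ± 5.04) and miR-493-5p (11110 ± 2480 and 19.5 ± 10.3). The levels of miR-412-5p (2305 ± 632) and miR-493-3p (2873 ± 117) in BE(2)C stood against values under the floor in Kelly. The list's median log2 change was -6.19. A different measure, the log2 ratio of line means without a pseudocount, had a median of -5.46 with values under each library's floor set to it. The camera adjusted p was 1.25e-69, and the adjusted p with an estimated correlation was 0.0364.

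**Figure D2:**
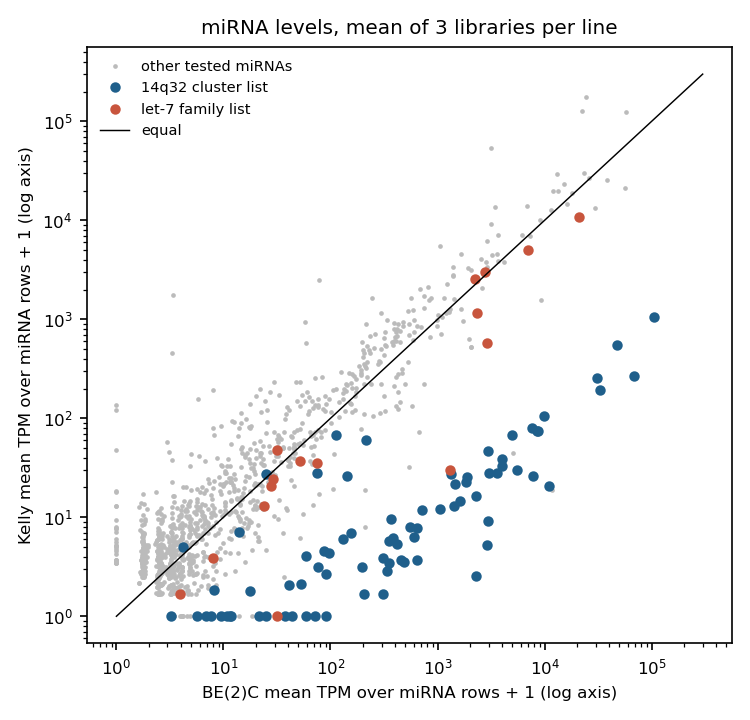
Mean TPM over miRNA rows + 1 of 3 libraries in BE(2)C (horizontal, log axis) and Kelly (vertical, log axis), with a point per tested miRNA and a line at equal levels. Of the 79 products of the 14q32 list 72 were higher in BE(2)C, and of the 16 let-7 products 6 were, with let-7c-5p and let-7c-3p far below the line.

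Other lists called by camera lost the call with an estimated correlation. Of 34 products of neuronal miRNAs, 16 rose in Kelly and 4 fell (18 and 4 adjusted over the list alone), led by the miR-129 products and miR-132-5p (42.2 ± 3.06 in Kelly, under the floor in BE(2)C), whose call was lost with a pseudocount of 0.1 (adjusted p = 0.0802). Its adjusted p was 0.00347, and 0.513 with an estimated correlation. Of 43 products of miRNAs known to be repressed by MYC, 16 rose in Kelly and 4 fell (20 and 4 over the list alone). Among them miR-30a-5p went from 16.9 ± 6.52 to 137 ± 16, miR-30a-3p from 28.6 ± 7.53 to 229 ± 43.9, and miR-22-5p from 7.75 ± 3.82 to 38.7 ± 13.4, a call lost with spike-in scaling (adjusted p = 0.0519). In contrast, miR-27b-3p fell from 55977 ± 2353 to 21171 ± 4823. Summed over its products, the list held 8.65% ± 0.220 of miRNA TPM in BE(2)C and 6.59% ± 1.16 in Kelly, opposite to most of its calls. The list's adjusted p was 0.0104, and 0.520 with an estimated correlation. At Xq26-27, 7 of 13 products of the clusters of miR-424 and miR-506 were higher in BE(2)C and 0 in Kelly, as over the list alone, among them miR-450b-5p (581 ± 31.9 and 133 ± 22.2) and miR-450a-5p (410 ± 39.5 and 132 ± 24.4). The call of miR-450a-1-3p, with a mean under the floor in both lines, was lost without Kelly replicate 1, 2 or 3 (0.0615 to 0.0886). The list's adjusted p was 0.0109, and 0.513 with an estimated correlation. Its median log2 change was -1.08. A different measure, the log2 ratio of line means without a pseudocount, had a median of 0.00317 with values under each library's floor set to it. Of the 13 products, 4 were under the floor in all libraries.

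Camera called none of the other lists. Of 20 products of the oncogenic miR-17-92 cluster and its paralogs, 7 rose in Kelly (9 over the list alone, adjusted p = 0.0507), including miR-18a-3p (53.7 ± 6.5 to 173 ± 36.6), whose call was lost with spike-in scaling (adjusted p = 0.0700). The rise of miR-20a-3p, under the floor in Kelly, lost its call without BE(2)C replicate 1, 2 or 3 (0.0780 to 0.109). Of 9 miR-99-100-125 products 4 fell and 1 rose, as over the list alone (adjusted p = 0.0803). Of 8 p53-linked products 4 rose and 1 fell (4 and 2 over the list alone, adjusted p = 0.321), the fall being miR-215-5p (670 ± 98.6 to 71.8 ± 33.1). The rise of miR-34a-3p, under the floor in Kelly, lost its call without BE(2)C replicate 1, 2 or 3 (0.132 to 0.209). That call was also lost with the replicate block (0.0796), quantile normalization (0.0865), spike-in scaling (0.0839), median-ratio scaling (0.0549) and voom (0.104). Of 8 products of HOX cluster miRNAs 4 rose and 2 fell, as over the list alone (adjusted p = 0.813), with miR-196a-5p at 209 ± 40.3 in BE(2)C and 7.05 ± 3.41 in Kelly. Of the rises, miR-10a-3p and miR-10b-3p lost their calls without BE(2)C replicate 1 (0.0991 and 0.0867), 2 (0.116 and 0.0544) or 3 (0.0822 and 0.0594) and with spike-in scaling (0.0552 and 0.292), and miR-10b-3p also without Kelly replicate 1, 2 or 3 (0.0811, 0.0548 and 0.134). The miR-181 family had 3 rises among 8, as over the list alone (adjusted p = 0.508, median log2 change -0.05, mean 0.88), including miR-181d-5p (50.8 ± 12.2 to 234 ± 68.0). That of miR-181c-5p was lost without BE(2)C replicate 1, 2 or 3 (0.0566 to 0.0633). The C19MC cluster had 2 rises among 6, as over the list alone (adjusted p = 0.315), including miR-524-5p (23.3 ± 10.6 to 148 ± 96.4), and the miR-183-96-182 cluster 0 calls among 3 (adjusted p = 0.709). The pluripotency clusters, miR-221-222 and the liver marker miR-122 had 1 measured product each, none past the threshold.

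Markers of other cell types did not move together. Of 12 mesenchymal products 5 were higher in BE(2)C, as over the list alone (adjusted p = 0.0790, median log2 change 0.04, mean -0.90). These included miR-199a-5p (9206 ± 727 and 1568 ± 1127) and miR-214-3p (211 ± 26.9 and 18.1 ± 7.47), both made from DNM3OS on chromosome 1, though miR-199a-5p has a further locus on chromosome 19. The 3p rows of miR-199a and miR-199b, compared after their values were seen, were nearly equal (2039 and 2044 TPM in BE(2)C, 520 and 520 in Kelly). They may hold the same reads, so the 5 mesenchymal calls need not be separate results. This also limits the arm ratio of miR-199b, which limma called (adjusted p = 0.00650). Of 4 blood products 3 rose in Kelly and 1 fell, as over the list alone (adjusted p = 0.321), with miR-486-3p at 31.9 ± 11.5 and 170 ± 39.5. The other rises, miR-486-5p and miR-142-3p, lost their calls without BE(2)C replicate 2 (adjusted p = 0.146 and 0.221) or 3 (0.103 and 0.140) and with the replicate block (0.0614 and 0.0841). The call of miR-486-5p was also lost without Kelly replicate 3 (0.132), and its log2 change of 0.70 went to 0.37 with median-ratio scaling (0.291) and to 0.078 with spike-in scaling (0.896). Lost too was that of miR-142-3p without BE(2)C replicate 1 (0.186). The fall, miR-155-5p, lost its call without Kelly replicate 1, 2 or 3 (0.0561 to 0.0827). In all 6 libraries 2 of the 4 products were under the floor, which are miR-155-5p and miR-142-3p (2.44 ± 0.532 in Kelly). Of 4 epithelial products 1 rose and 1 fell, as over the list alone (adjusted p = 0.664), with miR-200c-3p at 48.1 ± 10.7 and 147 ± 2.86, a call lost with spike-in scaling (adjusted p = 0.0697). The fall was that of miR-200b-3p, with a mean under the floor in BE(2)C and listed at 0 in Kelly, and its call was lost without Kelly replicate 1, 2 or 3 (0.103 to 0.138), with the replicate block (0.0638) and with voom (0.0871). Of 6 muscle products 1 rose (3 over the list alone, adjusted p = 0.106), with miR-499a-3p at 531 ± 204 and 1200 ± 240. Its call was lost without Kelly replicate 2 or 3 (adjusted p = 0.0538 and 0.0744) and with spike-in scaling (adjusted p = 0.442).

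Counted over all alternatives in which a miRNA was tested, 21 of the 68 called named miRNAs lost the call at least once. Of 17 alternatives, let-7d-5p and miR-10b-3p lost it in 10, miR-486-5p in 8, miR-499a-3p in 4, let-7i-5p and miR-92a-3p in 3, miR-18a-3p and miR-18a-5p in 2, and let-7a-5p, miR-22-5p, miR-125b-1-3p, miR-132-5p and miR-200c-3p in 1. Of 12 alternatives, miR-34a-3p and miR-142-3p lost it in 11, miR-200b-3p in 8, miR-10a-3p in 7, miR-450a-1-3p in 6, miR-20a-3p in 5, and miR-155-5p and miR-181c-5p in 4.

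The balance between the arms of a hairpin differed in 7 of 110 hairpins by limma, 6 toward the 5p arm in Kelly and 1 toward the 3p arm. A pseudocount of 5 gave 25 hairpins, 17 toward 5p and 8 toward 3p, and a mean of at least 50 TPM in both arms gave 8 of 55, 5 toward 5p and 3 toward 3p. Among the 7 called hairpins, all but miR-199b, whose limit is given above, are from 14q32, whose products were low in Kelly. They include miR-539 and miR-487a, named after their values were seen. In Kelly, miR-539-5p (3.61 TPM) and both arms of miR-487a (3.36 and 4.41) were under the floor. Ratios with an arm under the floor are not read as a change in arm use. The named examples are all from 14q32. In miR-410 the 5p arm was at 215 TPM and the 3p arm at 1617 in BE(2)C, against 59.5 and 13.5 in Kelly (change in log2 ratio 5.21, SE 0.43, adjusted p = 0.00138). In miR-487b the arms were at 113 and 1439 in BE(2)C and 66.5 and 11.9 in Kelly (adjusted p = 0.00793), and in miR-377 at 73.3 and 306 against 27.2 and a 3p arm under the floor (adjusted p = 0.00662). Toward the 3p arm, miR-369 went from 481 and 1324 to a 5p arm under the floor and 26.3 (adjusted p = 0.00886), a call lost with a pseudocount of 5 (adjusted p = 0.180) and without BE(2)C replicate 2 (0.0559).

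The spike-in series asked whether added RNA was recovered in proportion and whether endogenous miRNAs moved with it. All 6 spike-ins together rose with a slope of 1.06 in BE(2)C and 1.05 in Kelly on log scales, where 1 is proportional. A slope over these evenly spaced levels rests on 500 and 5 alone. The single steps were uneven. From 50 to 500 the spike-ins rose 14.5-fold in BE(2)C and 9.29-fold in Kelly, and from 5 to 50 they rose 9.09-fold and 13.8-fold. LET7I held 70.7% ± 1.60 of spike-in TPM in BE(2)C and 71.7% ± 1.98 in Kelly, followed by miR-Neg (22.5% and 21.8%) and LET7A2 (6.11% and 5.85%). The slopes of single spike-ins ran from 0.85 (mirNegDH2 in BE(2)C) to 1.34 (mirNegDH1 in Kelly), and MIR17 gave 0.89 in both lines. At level 5, mirNegDH1, mirNegDH2 and MIR17 rested on an estimated 1 to 7 reads.

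No miRNA passed the threshold for a change with spike-in level by limma (0 of 1217, 83 at an unadjusted p under 0.05, smallest adjusted p = 0.718), and 0 differed in slope between the lines (25 unadjusted). With 1 library per level in each line, small changes can be missed. The median log2 slope per unit of log10 concentration was -0.143. Fewer miRNA rows were above 0 at level 500 than at 5, with 977 and 1280 in BE(2)C and 1116 and 1219 in Kelly. Without a filter there was 1 call, and a fit of levels 500 and 5 alone gave 12, of which 11 fell with rising level.

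**Figure D3:**
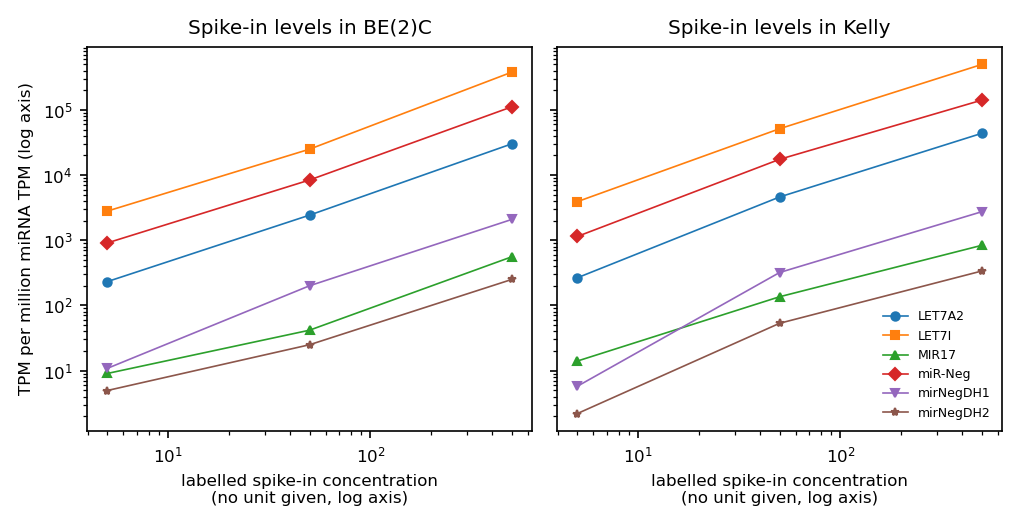
TPM of each of the 6 spike-ins per 1000000 miRNA TPM (log axis) against labelled concentration (log axis, no unit given), with a point per library and the points of a spike-in joined, for BE(2)C on the left and Kelly on the right. Levels rise over the whole range, with LET7I highest and mirNegDH2 lowest in both lines.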

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

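Median-ratio scaling, the deposited TPM, voom on estimated reads, single spike-ins, and leaving out the level 500 libraries or single miRNAs were chosen after the data were seen. The main count of 292 differing miRNAs lay between 221 and 356 with quantile normalization, spike-in scaling, other filters and pseudocounts, median-ratio scaling, voom and without the level 500 libraries. It was 185 with arms and copies summed, where fewer values are tested, and 183 on the deposited TPM, with 74 higher in Kelly, as spike-ins there lower the values of some libraries. Spike-in scaling left 67 higher in Kelly and turned the sign of 2 called miRNAs. Leaving out each library gave 194 to 243 calls, 82 to 125 higher in Kelly and 93 to 132 higher in BE(2)C, the fewest in total without BE(2)C replicate 2 (194), in Kelly without Kelly replicate 3 (82) and in BE(2)C without BE(2)C replicate 3 (93). These fits have fewer samples. Of 68 named miRNAs past the threshold, 47 kept call and direction in each setting run for them, and 0 turned direction. Among those not past it, direction turned as follows, and the cause was not tested. Spike-in scaling gave log2 changes of -0.46 for let-7e-5p, -0.091 for let-7e-3p, -0.51 for let-7g-5p, -0.26 for miR-99b-5p and -0.56 for miR-183-5p. Median-ratio scaling gave -0.17 for let-7e-5p, -0.22 for let-7g-5p and -0.26 for miR-183-5p, the deposited TPM -0.00495 for miR-183-5p, and quantile normalization 0.28 for let-7f-5p. With single libraries left out, values ran from -0.58 to 0.045 for let-7f-2-3p, -0.00791 to 0.24 for let-7g-5p, -0.79 to 0.51 for miR-371a-3p, -0.12 to 0.26 for miR-183-5p and -0.34 to 1.18 for miR-122-5p. As miR-371a-3p and miR-122-5p were under the floor in both lines, their fitted values are not read as folds. Of 7 lists called by camera, 1 remained with an estimated correlation, while fry, which does not compare a list with other miRNAs, called 14. Hairpins with a changed arm ratio numbered 25 with a pseudocount of 5 in place of 0.5 and 5 to 8 with single libraries left out. Spike-in slope calls rose from 0 to 1 without a filter and to 12 from levels 500 and 5 alone, a fit with few residual degrees of freedom. The let-7 share difference stayed between -1.28 and -1.86 percentage points over the alternatives, and the let-7 ratio per spike-in between 2.45 and 2.90 with single libraries left out. None of the share alternatives left out the 14q32 products as a set. Slopes of the spike-ins as a share of the table were 0.970 and 0.942. Whether levels pair the libraries cannot be told. Deviation correlations were 0.25, 0.04 and -0.15 at 500, 50 and 5, and -0.28 to 0.32 between different levels. Deviations from a mean of 3 libraries constrain each other. With the level as a replicate block there were 262 calls, 138 higher in Kelly and 124 in BE(2)C, 7 arm ratios and 7 lists. DESeq2 and voom on raw counts were not run. Depth limits statements on miRNAs under the floor of 3 reads, 6.28 to 9.52 TPM.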

Other observations

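Genomic clusters were examined after the data were seen, as 21 groups of 4 or more single-locus products within 50000 bases on one strand. Most products described here, those in AATK excepted, also belong to the MYC-repressed, neuronal, let-7 or miR-99-100-125 lists. The miR-23b-27b-24-1 cluster in C9orf3 (chromosome 9, 95085208 to 95086088) had 4 of 5 products higher in BE(2)C, and held 5.72% of miRNA TPM there and 2.15% in Kelly. Its miR-23b-3p stood at 742 ± 83.7 TPM in BE(2)C and 220 ± 76.6 in Kelly (log2 change -1.80, limma adjusted p = 0.00160). Its paralogous cluster miR-23a-27a-24-2 (chromosome 19, 13836287 to 13836659) had 0 of 5 past the threshold, and held 0.296% and 0.291%. The miR-99b-let-7e-125a cluster in SPACA6 (chromosome 19, 51692612 to 51693339) had 0 of 6, next to the falls of let-7c and miR-99a on chromosome 21. The miR-132-212 cluster (chromosome 17, 2049908 to 2050380) had 3 of 4 products higher in Kelly, with miR-132-3p at 19 ± 4.66 and 167 ± 33.9 TPM (log2 change 3.08, adjusted p = 0.000203). In AATK (chromosome 17, 81125276 to 81133308), miR-338-5p went from 8.44 ± 1.12 to 82.0 ± 23.6 TPM (log2 change 3.10, adjusted p = 0.000497).

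Of the tests below, the one on miR-7-1-3p was chosen before its values were seen, and the others after. The first pattern is that miR-3529-3p held up to 208095 TPM while miR-7-5p stayed under 100. MIR3529 (chromosome 15, 88611847 to 88611924) lies inside MIR7-2 on the opposite strand, and among other antisense pairs miR-103b (13453 ± 1873 and 19835 ± 7122 TPM) lay above miR-103a-3p (6125 ± 1417 and 7109 ± 773), miR-374c-3p (1222 and 2293) above miR-374b-5p (192 and 276) and miR-3184-3p (1645 and 4575) above miR-423-5p (214 and 323), but miR-3184-5p (213 and 889) below miR-423-3p (3437 and 13595). A random spread of reads between both rows is argued against, since miR-3529-3p held at least 99.8% of their sum in 6 of 6 libraries. Reads of miR-7-5p placed on the antisense row may explain the pattern, but the passenger miR-7-1-3p lay above miR-7-5p in 1 of 6 libraries, and its change between lines was smaller than that of miR-3529-3p by 2.29 (SE 0.49) on the log2 scale, while miR-7-2-3p, the passenger of MIR7-2 itself, was under the floor in BE(2)C (2.47 ± 2.23 TPM) and at 13.3 ± 5.27 in Kelly. The bound set beforehand was met (miR-7-5p minus miR-7-1-3p 13.8 ± 17.6 TPM). It cannot decide, because a passenger can lie below its guide also where guide reads are placed elsewhere. The smaller change of miR-7-1-3p cannot decide either, because miR-7-5p is also made from MIR7-2 and MIR7-3. A condition that the bound be met by more than its spread was applied after that result was seen. The explanation stays open, as does a real antisense product.

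The second pattern is the low remainder of 14q32 products in Kelly. Carry-over of BE(2)C reads is argued against as the whole source, because it would leave 1 ratio for all products. Among 29 products at 1000 TPM or more in BE(2)C, the Kelly level was 0.0664% to 1.99% of that in BE(2)C, against 0.154% ± 0.0476 for miR-99a-5p, and 23 lay more than 2 times above miR-99a-5p in all 3 Kelly libraries. Without the 3 products of highest ratio, which are scarce in BE(2)C, 97.2% of the Kelly 14q32 TPM was left, so those 3 held little of it. Without the 3 most abundant in Kelly, 45.4% was left. That value cannot decide, as these (miR-381-3p, miR-370-3p and miR-127-3p) also led 14q32 in BE(2)C. Their ratios of 0.994%, 1.17% and 0.394% lay within the range above. Reads of other origin on single products stay open. The 5p arms of miR-487b, miR-377 and miR-410, whose arm ratios differed, were among the 6 highest ratios at 59.0%, 37.1% and 27.7%. Weak expression in Kelly and a few cells of another kind in the culture may each account for the remainder and were not tested.

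The third pattern is let-7i-5p at 3148 TPM in the BE(2)C library with spike-ins at 500, against 2079 and 1795 at 50 and 5. Reads of the LET7I spike-in placed on let-7i-5p may be the cause. In Kelly, let-7i-5p was at 963 TPM at level 50 and 1230 at level 5. A leak of 0.357% of LET7I would raise the 1230 to 3009 TPM in the Kelly library at 500. Found there was 1314 TPM, or 43.7% of a prediction that includes the 1230. This meets the bound against a leak, but the requirement of more than 1 library per line was applied after that result was seen, and with it the leak and a spread between libraries cannot be told apart.

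Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 292 miRNAs and the highest other 0, so 1 split was as large. For arm ratios the values were 7 and 0, again with 1 split as large. For lists they were 7 and 7, with 2 splits as large, the other one grouping BE(2)C 500, BE(2)C 50 and Kelly 500.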
